A study of Saccharomyces cerevisiae with 44 samples.

How the data were processed

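Messenger RNA of the budding yeast Saccharomyces cerevisiae, strain CEN.PK122, was measured over the yeast metabolic cycle, in which a continuous culture fed glucose alternates between phases of high and low respiration. Per the labels' protocols, the cultures grew in fermentors on medium with 1% glucose. The fast cycling condition had a dilution rate of 0.12 to 0.13 per hour and the slow cycling condition one of 0.045 to 0.05 per hour. Fast samples were taken every 13 min (20 libraries) and slow samples every 36 min (24 libraries), in each case over 2 cycles. With 20 and 24 points over 2 cycles, the nominal period was 10 intervals (130 min) in the fast and 12 intervals (432 min, or 7.2 h) in the slow condition. The labels name no replicate cultures, so each condition was treated as 1 culture, and the p-values measure the spread between time points of that culture. Per the labels' protocols, total RNA received external control RNAs of the ERCC set before poly(A) selection, stranded libraries were made, and samples were randomised over 4 groups for RNA extraction. The group of each sample is not given in the sources used here.

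The authors deposited 1 table of RPKM values (reads per kilobase of gene body, scaled to library size). Per the file headers, HOMER counted reads on the sense strand over whole gene bodies of an SGD annotation of build sacCer3 joined to the 92 control sequences. Per the submitters' processing notes, FastQC 0.10.1 and TopHat2 2.0.10 were also used. How reads with several matches were treated is not given in the sources used here, so values of near-identical paralogs (ribosomal protein pairs, histones) are uncertain. The deposited table also gives the length of each gene body in bases, which was used as deposited. All 44 value columns matched the labels of 1 sample each. Of the 6008 yeast rows found in the reference gene table, 6000 (99.87%) had the same start and end, and coordinates are those of the file.

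The table has 6784 rows, of which 92 are controls. Yeast genes with a mean of at least 1 RPKM over the 44 libraries were tested (5820 of 6692). Low RPKM values fell on whole multiples of what 1 read is worth within a tolerance of 0.1 in 100.0% of values checked in every library, which gave the depth. It was 7.6 to 19.67 M reads in the fast and 6.45 to 13.11 M in the slow libraries. RPKM values are shares of a library, so a burst in abundant genes lowers the values of others.

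Cycling was tested with an own implementation of the rank test that the study's design text names (JTK_Cycle), with an exact null distribution, Bonferroni correction over periods and phases and Benjamini-Hochberg adjustment over genes (q under 0.05). Periods of 9, 10 and 11 intervals were allowed in the fast and 11, 12 and 13 in the slow condition. Peak-to-trough range and phase came from a cosine fitted to log2(RPKM + 1) at the nominal period, so ranges understate the change of low genes. The profile range is the highest minus the lowest value of the mean of the 2 cycles. Differences in range were tested with a z test on delta-method errors. Levels were compared with limma 3.58.1 (R 4.3.3) on log2(RPKM + 1), with q under 0.05 and at least 2-fold. Other tests were Fisher's exact test for overlaps and lists, and permutation tests (100000 draws, or 10000 random lists) for phases, expression and length. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Phases are given as a share of a cycle from the first sample; the labels do not align the starts of the conditions.

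On simulated data with 5820 genes, the cycling test called at most 0.107% of unchanged genes. In the fast design it recovered 15.5% of genes with a cosine range of 0.5 on the log2 scale, 87.0% with 1.0 and 98.5% with 2.0. In the slow design it recovered 58.0%, 96.0% and 100.0%. The test of range differences recovered 199 (99.5%) of 200 genes changed by 1 on the log2 scale, with 20 false calls. Its simulation gave every gene the same Gaussian noise, without read counts or depth. In the real data the SE of the range difference varied between genes, with a median of 0.24 on the log2 scale. This recovery therefore does not cover noisier genes. In the simulations of cycling and of range differences all cycling courses were pure cosines. In the real data the cosine took a median of 75.2% of the variance of cycling genes in fast and 44.9% in slow. These recovery figures therefore do not cover other waveforms. The level test recovered 99 of 100 genes changed by 1.5 and 100 of 100 changed by 2 on the log2 scale, with 0 false calls at this threshold and 9 at q under 0.05 with no minimum fold.

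Before the data were examined, the tests, 22 gene lists and the rule for named genes were fixed. The rule took, per condition, the 6 cycling genes with the largest range and a correlation between cycles of at least 0.5, the 2 cycling members of each list with the largest range, and RPL17B, MRPL10, POT1 and ACT1. For level it took the 10 highest and 10 lowest genes and the most changed member of each list, and for range differences the 5 largest in each direction, in each case with a mean of at least 10 RPKM. Alternatives covered scaling by median of ratios and by the controls, filters, pseudocounts, periods, thresholds, harmonic regression, removal of a linear trend and leaving out each library. For level they also covered cycle position as a covariate and each cycle alone. A repeat test without a template and the removal of slow time points 12 and 24 were added after the data were seen.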

Results

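The series followed gene expression through the yeast metabolic cycle at a high and a low dilution rate, with 20 libraries in the fast and 24 in the slow cycling condition. The design text states that cycling genes were sought. Depth averaged 11.5 ± 2.73 M reads (SD, n = 20) in the fast and 9.95 ± 1.56 M (SD, n = 24) in the slow libraries. The external control RNAs took 0.988 ± 0.33% of gene reads (SD, n = 20) in the fast and 1.09 ± 0.152% (SD, n = 24) in the slow libraries.

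**Figure D1:**
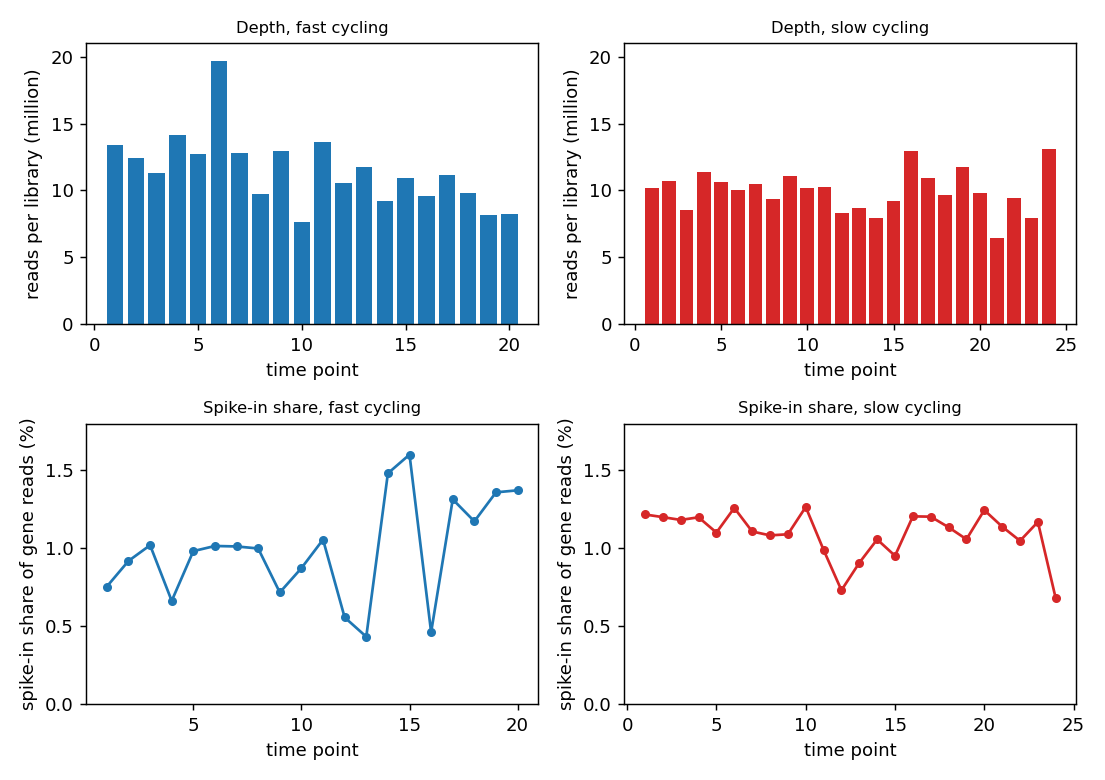
Reads per library in M (bars) and the share of gene reads taken by control RNAs in percent (points), by time point, for the fast (blue) and slow (red) condition. The control share ran from 0.433% to 1.601% in the fast libraries and from 0.679% to 1.265% in the slow ones, where the lowest values fell at time points 12 and 24.

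In the fast condition, the 6 genes with the largest cosine range among those named by the rule were ADH2, CTT1, FAT3, CTA1, FOX2 and ADY2; by profile range, NSR1 (6.06 on the log2 scale) exceeded all of these but ADH2 (6.34) and FOX2 (6.22). ADH2, an alcohol dehydrogenase that consumes ethanol (YMR303C, sacCer3 chromosome XIII, 873291 to 874337), moved between 67.0 ± 11.7 and 5485 ± 401 RPKM (mean ± SD of 2 cycles). Its cosine range was 6.45 ± 0.72 on the log2 scale (SE). The catalases CTT1 and CTA1 had ranges of 6.07 ± 0.43 and 6.00 ± 0.70 (SE), the fatty acid uptake gene FAT3 6.03 ± 0.61, the beta-oxidation enzyme FOX2 5.98 ± 0.87 and the acetate transporter gene ADY2 5.94 ± 0.72. All 6 peaked at time points 2 to 4 of the cycle.

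Genes of the cytosolic ribosome and its assembly peaked in a short window of the fast cycle. All 137 cytosolic ribosomal protein genes cycled (137 adjusted over the list alone) and 134 of them peaked at time point 8, which lies 91 min after the first sample. All 89 ribosome biogenesis genes cycled (89 adjusted over the list alone) and peaked there, with a median profile range of 19.7-fold; the nucleolar protein gene NSR1 ran between 7.30 ± 0.332 and 595 ± 317 RPKM (SD of 2 cycles). Of the 67 mitochondrial ribosomal protein genes, 67 cycled (67 adjusted over the list alone), with 39 at their maximum at time point 10. Elongation factor gene YEF3 (range 4.19 ± 0.37, SE) and the S-adenosylmethionine synthetase gene SAM1 (4.99 ± 0.43) also peaked at time point 8. All 24 heat shock and chaperone genes cycled (24 adjusted over the list alone), among them HSP12 between 482 ± 24.5 and 16720 ± 844 RPKM (SD of 2 cycles).

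Over all genes, 4281 of 5820 (73.6%) cycled in the fast condition in the exact rank test, and 2416 of them had a cosine range of at least 2-fold. Time point 8 held the maximum of 1415 genes (33.1%). The best period was 10 intervals for 2774 of the cycling genes, 11 for 1144 and 9 for 363. Scaling to the control RNAs, whose share varied irregularly between fast libraries, left 1407 cycling genes, of which 1404 were among the 4281.

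In the slow condition, the largest cosine ranges among genes named by the rule were those of YDL218W, YOR248W, SRL1, INO1, DSE4 and EGT2. By profile range, GRE1 (5.46 on the log2 scale), SAM1 (5.24) and NSR1 (5.22) exceeded YOR248W (4.85), SRL1 (4.86), INO1 (4.66) and EGT2 (5.05). YDL218W (chromosome IV, 66493 to 67446) had a range of 5.72 ± 0.47 on the log2 scale (SE), and its profile ran from 16.1 ± 10.1 to 881 ± 121 RPKM (SD of 2 cycles). The mannoprotein gene SRL1 (YOR247W, chromosome XV, 797676 to 798308) had a range of 4.60 ± 0.39, and YOR248W one of 4.64 ± 0.41. These overlap by 296 bases on the same strand, so their values are not independent. The inositol synthesis gene INO1 (4.44 ± 0.46) and the septum genes DSE4 (4.08 ± 0.48) and EGT2 (3.99 ± 0.48) followed.

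Genes of the cytosolic ribosome and its assembly peaked together at 1 slow time point. Of the 137 cytosolic ribosomal protein genes, 109 cycled (117 adjusted over the list alone), and all 109 peaked at time point 12, at 396 min. For ribosome biogenesis it was 78 of 89 genes (84 adjusted over the list alone), again with all 78 at time point 12. The 67 mitochondrial ribosomal protein genes all cycled (67 adjusted over the list alone) and 64 peaked at time point 1 of the cycle; MRPL7 had a range of 1.99 ± 0.26 on the log2 scale (SE). The lysine synthesis gene LYS9 ran between 68.6 ± 22.8 and 1480 ± 85.2 RPKM (SD of 2 cycles), with its peak at time point 12.

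The slow condition had 3196 cycling genes of 5820 (54.9%), of which 1164 had a cosine range of at least 2-fold; 1295 (40.5%) peaked at time point 12 and 755 (23.6%) at time point 1. A repeat test without a template, chosen after the data were seen, called 4975 genes against 4740 in the fast condition, and scaling to the control RNAs left 2529 against 1407, so both turn the order of the conditions. Leaving out time points 12 and 24, where the control share was lowest, left 2926. Removing a linear trend left 2172 and q under 0.01 left 2186. The median width at mid-height was 2 of 12 time points in the slow and 4 of 10 in the fast condition, and the cosine took 44.9% and 75.2% of the variance. Of the 3196 slow genes, 1696 had their best period at 13 intervals, the longest allowed, 1238 at 12 and 262 at 11. Ranges and phases were nonetheless fitted at the nominal 12 intervals.

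**Figure D2:**
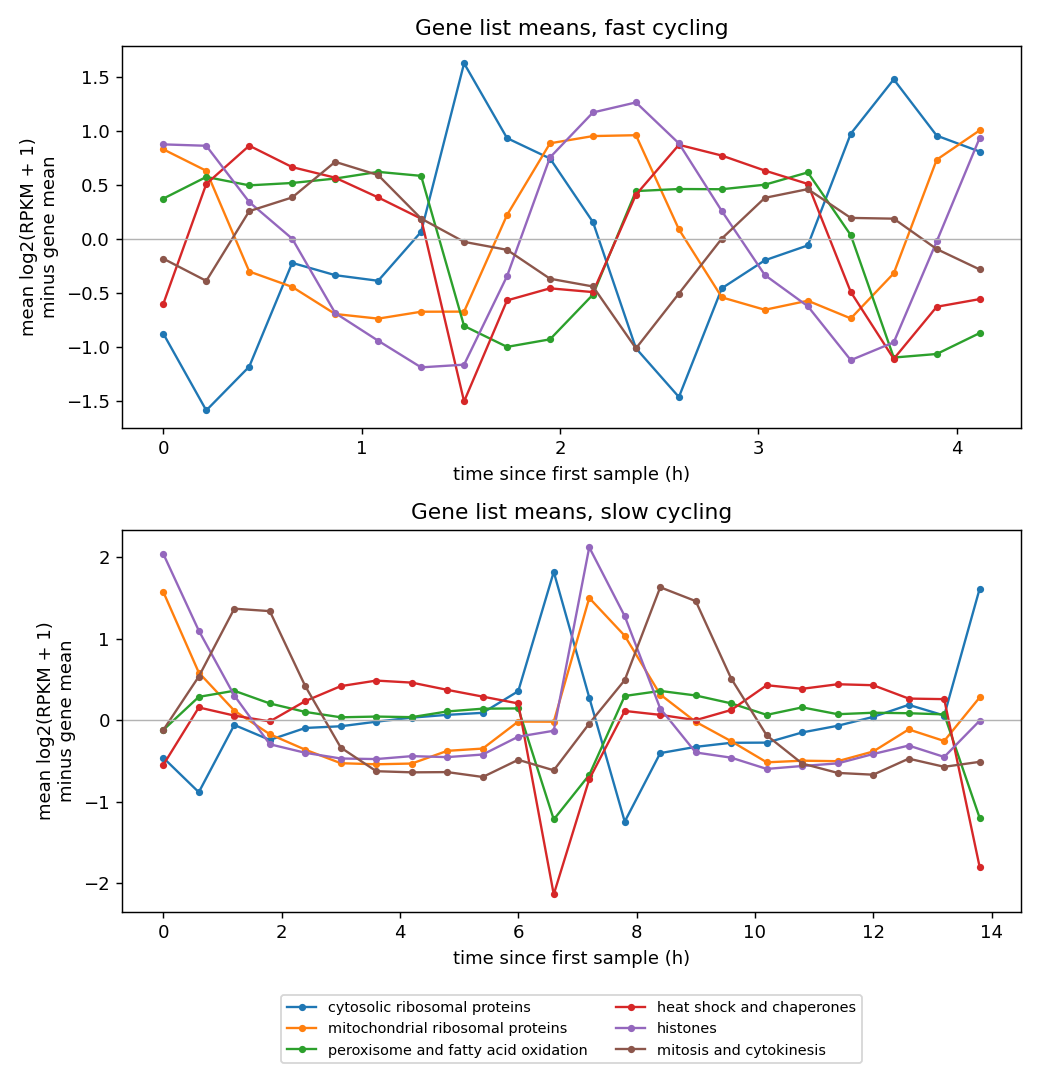
Mean of log2(RPKM + 1) minus each gene's own mean, over the genes of 6 lists, against hours since the first sample, in the fast (top) and slow (bottom) condition; each point is 1 library. Cytosolic ribosomal protein genes reached 1.63 at fast time point 8 and 1.82 at slow time point 12, where heat shock genes stood at -1.51 and -2.14.

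The 3 genes chosen as markers of the phases of the cycle kept distinct times. RPL17B, for a protein of the large cytosolic ribosomal subunit (YJL177W, chromosome X, 90786 to 91657), peaked at 632 ± 13.5 RPKM at fast time point 8 and at 806 ± 82.4 at slow time point 12 (SD of 2 cycles). MRPL10, for a mitochondrial ribosomal protein (YNL284C, chromosome XIV, 103134 to 104102), peaked at 273 ± 15.3 and 364 ± 63.5 RPKM, at time point 1 in both. POT1, for the thiolase of beta-oxidation (YIL160C, chromosome IX, 40191 to 41444), ran between 16.6 ± 1.78 and 608 ± 28.8 RPKM in the fast and between 88.0 ± 26.7 and 917 ± 45.5 RPKM in the slow condition (SD of 2 cycles). It missed the threshold in the slow condition (exact JTK test, q = 0.479) and passed it under harmonic regression. The actin gene ACT1 missed it in both (exact JTK test, q = 0.464 and 0.344), with ranges of 0.23 ± 0.08 and 0.22 ± 0.07 on the log2 scale (SE).

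**Figure D3:**
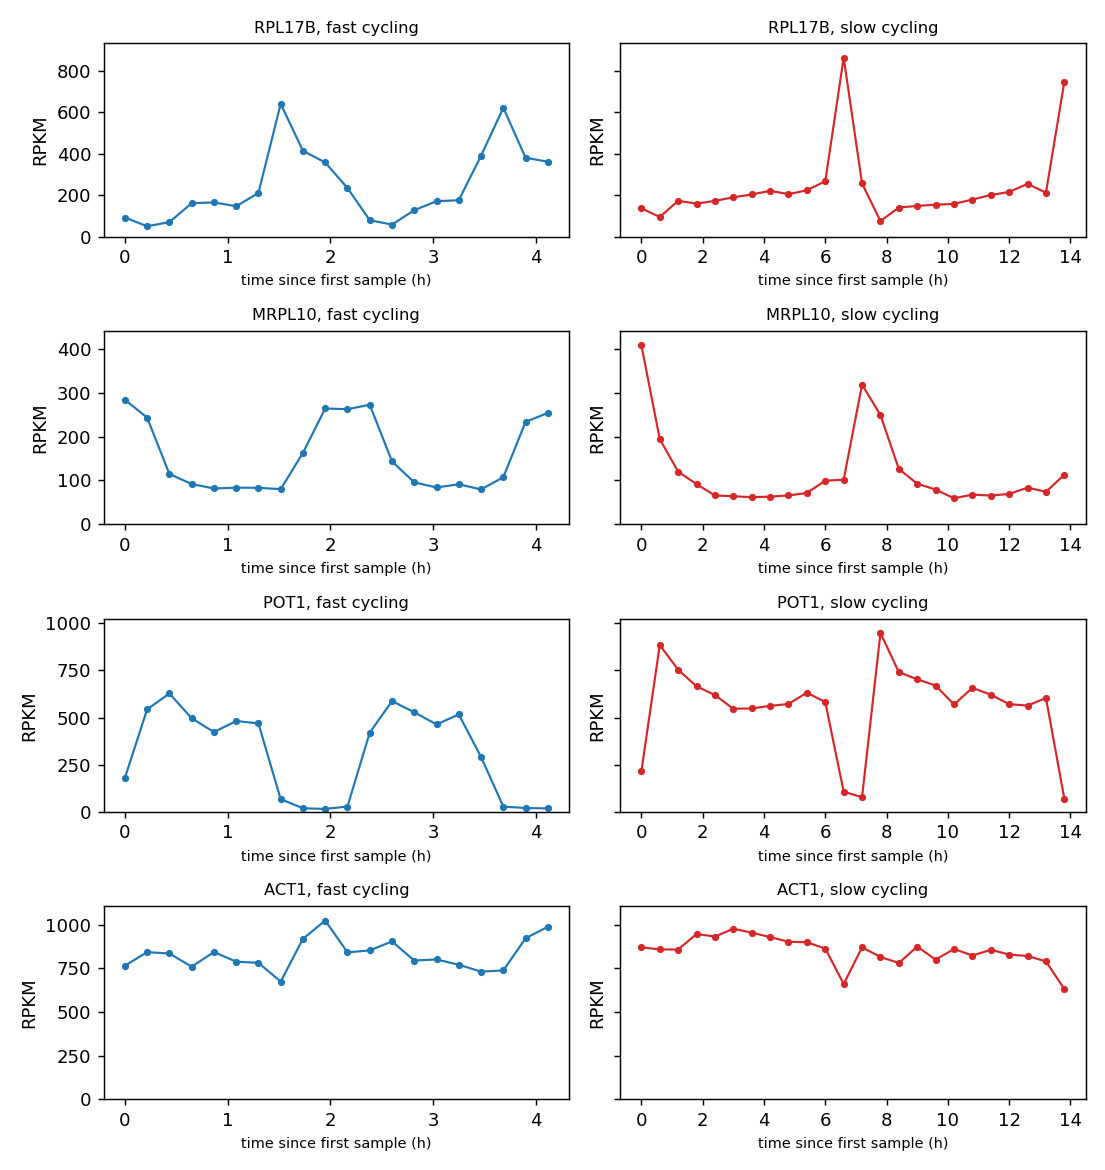
RPKM of RPL17B, MRPL10, POT1 and ACT1 (linear axes from 0) against hours since the first sample in the fast (blue) and slow (red) condition; each point is 1 library and each row shares its axis. RPL17B peaked at 632 RPKM in the fast and 806 RPKM in the slow condition, as means of 2 cycles.

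Cycling genes of both conditions overlapped. Mitochondrial ribosomal protein genes cycled in full in each condition, and 2701 genes cycled in both, against 2350.9 if the sets were independent (odds ratio 3.61, one-sided Fisher's exact test across genes, p = 6.57e-98; genes are not independent replicates). Another 1580 genes passed in the fast and 495 in the slow condition alone, but in only 910 of the 1580 and 98 of the 495 did the test of the range difference itself pass in that direction. That test used cosine ranges. Of the 4776 genes cycling in at least 1 condition, 83.7% had a larger cosine range in fast, but 53.6% a larger profile range. Scaling to the control RNAs left 959 genes in both, q under 0.01 left 1720, removing a linear trend 1700 and requiring a 2-fold range 999, while the repeat test gave 4316.

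The second cycle repeated the first. Per gene, the correlation of log2 values between cycles had a median of 0.827 in the fast and 0.867 in the slow condition, across genes, which are not independent replicates. The highest median over circular shifts of the second cycle was 0.57 in the fast and 0.387 in the slow condition. Scaled to the control RNAs, the fast median was 0.026.

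Lists enriched among cycling genes in both conditions were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, sulfur amino acid metabolism (31 and 27 of 32 in fast and slow; 31 and 27 adjusted over the list alone) and other amino acid biosynthesis (41 and 34 of 45; 42 and 35 adjusted over the list alone). Translation factors (25 of 26), heat shock genes (24 of 24) and S phase genes (32 of 33) passed in the fast condition, with 25, 24 and 32 adjusted over the list alone. Oxidative phosphorylation (27 of 35) and mitosis (14 of 16) passed in the slow condition, with 28 and 14 adjusted over the list alone. Autophagy genes cycled less often than other genes in the fast (15 of 37, Fisher's exact test, adjusted p = 0.000183) and proteasome genes in the slow condition (4 of 33, adjusted p = 2.69e-06), with 9 and 2 adjusted over the list alone. With harmonic regression, the log2 odds of cytosolic ribosomal protein and ribosome biogenesis genes in the slow condition turned to -1.53 and -0.88, and translation factors, sulfur amino acid metabolism, S phase genes and autophagy no longer passed in the fast condition. With only genes of at least 10 RPKM, translation factors and other amino acid biosynthesis no longer passed in fast, nor oxidative phosphorylation and mitosis in slow; translation factors also did not pass after scaling to the control RNAs.

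The remaining lists did not pass in either condition. In fast and slow, cycling members were 9 and 8 of 11 for the tricarboxylic acid cycle (IDH1 range 2.40 ± 0.23 and 1.68 ± 0.45, SE), 17 and 16 of 21 for glycolysis and fermentation, 8 and 8 of 12 for gluconeogenesis, and 18 and 11 of 19 for trehalose and glycogen. They were 31 and 21 of 45 for peroxisomes, 4 and 3 of 7 for vacuolar proteases (PRC1 range 1.88 ± 0.21 and 1.18 ± 0.37), 9 and 5 of 9 for histones, and 19 and 16 of 20 for ergosterol synthesis (ERG4 range 3.43 ± 0.22 and 3.12 ± 0.49). For meiosis they were 7 and 5 of 9, and for reference genes 6 and 4 of 8. Adjusted over the list alone the counts were equal, except 11 for the tricarboxylic acid cycle in fast and 6 for histones in slow. PRE3, a proteasome subunit gene, had a range of 0.53 ± 0.11 and 0.53 ± 0.22.

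Mitosis genes had a later mean phase than heat shock genes in the fast cycle and an earlier one in the slow cycle; the order of single lists was not tested. In the fast cycle the mean phases of cycling members were 0.678 for ribosome biogenesis, 0.714 for cytosolic ribosomal proteins, 0.842 for S phase genes, 0.979 for mitochondrial ribosomal proteins, 0.079 for histones, 0.285 for heat shock genes and 0.495 for mitosis. In the slow cycle they were 0.749, 0.796, 0.938, 0.033, 0.044, 0.497 and 0.184. Members were more concentrated in phase than random sets of cycling genes for 14 of 21 lists in the fast and 15 of 19 in the slow condition (permutation, adjusted p under 0.05). Over the 2701 genes, phases in the conditions had a circular correlation of 0.676 across genes, which are not independent replicates (permutation p = 1e-05, the smallest possible), and 95.4% lay within 0.25 cycle of the mean offset of 0.094 cycle.

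**Figure D4:**
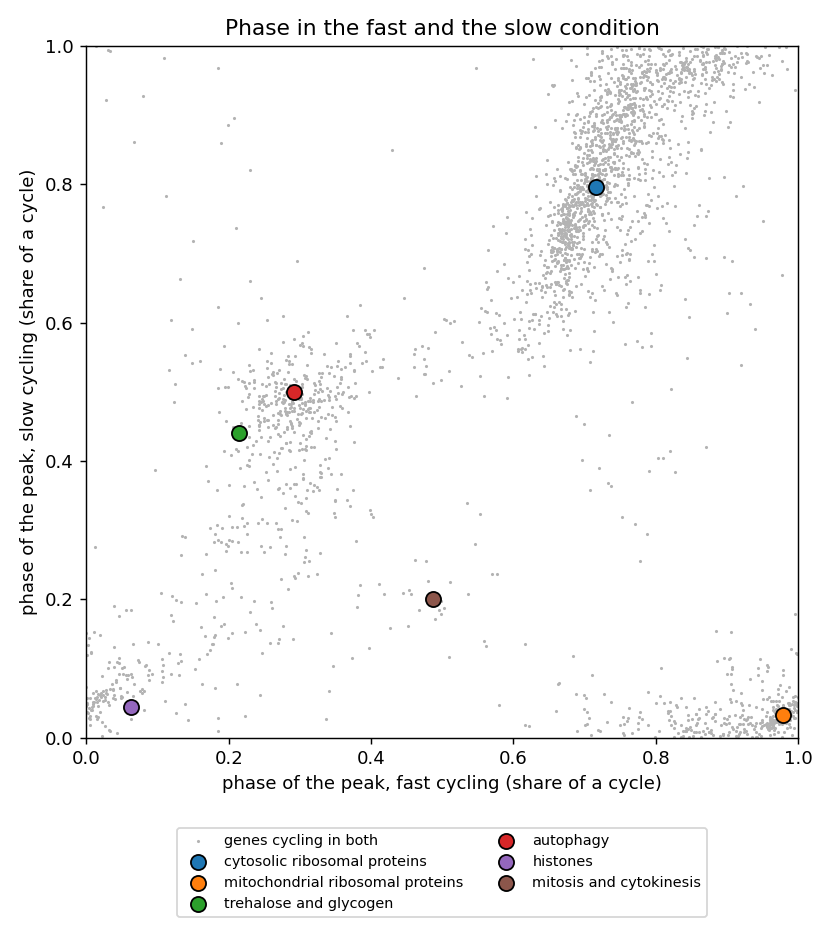
Phase of the peak as a share of a cycle in the fast (x) and slow (y) condition, for the 2701 genes cycling in both (grey points) and the mean of 6 lists (large points); both axes wrap at 1. Mitosis genes (0.487 in fast, 0.200 in slow) lie away from the main band, while cytosolic ribosomal protein genes (0.716 and 0.796) lie within it.

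Ranges differed between conditions in both directions. The largest excess of cosine range in the fast condition was in FAT3 (fast minus slow 4.66 on the log2 scale, q = 1.06e-06), ADY2 (4.62), FOX2 (4.26), POX1 (4.11) and CTA1 (4.09). Their profile ranges differed by less and in another order: 2.43 for FOX2, 2.25 for FAT3, 1.81 for ADY2, 1.65 for POX1 and 1.60 for CTA1. SRL1 (-3.28), YOR248W (-3.26), YDL218W (-3.15), the cell cycle repressor gene YHP1 (-2.88) and EGT2 (-2.48) swung more in the slow condition. For mitosis genes the range was larger in slow in 11 of 16, among them CLB1 (-2.46) and HOF1 (-1.73), and for cytosolic ribosomal proteins the cosine range was larger in fast in 132 of 137, with a median difference of 1.45. The profile range of the cytosolic ribosomal list differed by a median of 0.15, with 8.05-fold in fast and 7.16-fold in slow. Of 4776 genes, 1984 had a larger cosine range in the fast and 179 in the slow condition (z test, Benjamini-Hochberg q under 0.05). The median difference was 0.41, but 0.03 for the profile range; after scaling to the control RNAs, 251 and 40 genes passed.

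Levels were means of log2 values over both cycles. They therefore depend on how long a gene stayed high as well as on its peak, and peaks were not tested. The pheromone gene MF(ALPHA)1 (YPL187W, chromosome XVI, 193648 to 194145) had 374 ± 353 RPKM in the fast and 29.3 ± 19.8 in the slow condition (SD over time points, n = 20 and 24; limma log2 change 3.15 ± 0.34 SE, q = 4.4e-10). The iron uptake gene FET3 (2.76), the nitric oxide dioxygenase gene YHB1 (2.10), MFA2 (2.08), STE2 (2.02), DIP5 (1.91) and HTB2 (1.85) were also higher in fast. Lower in fast were SPS100 (-4.05), YDL218W (-3.84), GRE1 (-3.78), YPR145C-A (-3.60), PIR3 (-3.25), SIP18 (-2.55) and the heat shock gene SSA3 (-2.53).

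By list, past the threshold in fast were 5 higher of 16 mitosis genes, 4 higher of 32 sulfur genes, 4 of 33 S phase genes, 3 of 9 histone genes and 2 of 35 oxidative phosphorylation genes (5, 4, 4, 3 and 2 adjusted over the list alone). The oxidative phosphorylation median of 0.47 and the mitosis median of 0.73 lay above 100% of 10000 random lists matched on expression. Lower in fast were 6 of 24 heat shock genes (median -0.67), 3 of 45 peroxisomal genes (-0.31) and 2 of 21 glycolysis genes (-0.33), among them PDC6 (-2.04), with 6, 3 and 2 adjusted over the list alone. No gene passed among cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, the tricarboxylic acid cycle, autophagy, gluconeogenesis, trehalose and glycogen, vacuolar proteases, the proteasome or the reference genes, over all genes or adjusted over the list alone, at the 2-fold threshold. At q under 0.05 and any size, 21 of 37 autophagy genes were lower (median -0.35, percentile 0.0 of 10000 random lists), 7 of 11 tricarboxylic acid cycle genes were higher (0.41, percentile 99.4), and 2 of 67 mitochondrial ribosomal protein genes were higher (0.24, percentile 100.0). At that q, counts of higher genes at any size were also 33 of 35 for oxidative phosphorylation, 16 of 45 for other amino acid biosynthesis (median 0.39, percentile 100.0), 14 of 16 for mitosis (1 lower), 10 of 32 for sulfur metabolism, 7 of 20 for ergosterol synthesis, 7 of 33 for S phase genes (2 lower) and 5 of 9 for histones. Counts of lower genes were 16 of 24 for heat shock genes, 14 of 45 for peroxisomal genes (1 higher), 9 of 21 for glycolysis (3 higher) and 6 of 9 for meiosis (2 higher). Past the 2-fold threshold, other amino acid biosynthesis and ergosterol synthesis had 1 higher gene each, and meiosis 1 higher and 2 lower, with equal counts adjusted over the list alone. The medians of ribosome biogenesis (-0.14) and cytosolic ribosomal protein genes (-0.09) became 0.04 and 0.11 with scaling to the control RNAs, which still lay below the 0.20 by which that scaling moved the median of all genes. Over all genes, 109 were higher and 137 lower in the fast condition (limma, Benjamini-Hochberg q under 0.05, at least 2-fold), and 2225 of 5820 differed at any size. Of the 246 genes past the 2-fold threshold, 225 (91.5%) cycled in at least 1 condition, as did 82.1% of all tested genes. A higher level therefore need not mean a higher peak. Scaling to the control RNAs moved the median of all genes by 0.20 on the log2 scale and gave 170 higher and 97 lower.

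The title of the series concerns synthetic cost, so expression and length of cycling genes were compared with the rest. Cycling genes had a median of 59.5 RPKM against 38.2 in the fast and 57.8 against 44.1 in the slow condition (mean log2 difference 0.96 and 0.60, permutation p = 1e-05 for both, the smallest possible, adjusted 2e-05). Cycling genes took 83.1% and 65.8% of gene reads. The RPKM values compared are means over time points, which a burst raises by itself. Gene bodies of cycling genes did not differ detectably in the fast condition (difference 0.04 on the log2 scale, permutation p = 0.2) and were longer by 0.11 in the slow one (permutation p = 0.0001, adjusted 0.0002). The fast difference passed the threshold in both directions under alternatives: 0.07 at q under 0.01, 0.15 with harmonic regression, 0.62 with the repeat test and -0.14 with only genes of at least 10 RPKM, where the slow difference was -0.01.

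Of 46 control RNAs with at least 1 RPKM, 0 cycled in either condition by the exact JTK test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 0 in the fast and 1 in the slow condition as deposited, and 2 and 0 after scaling to their own total. Their total share had a coefficient of variation of 33.4% in the fast and 13.9% in the slow condition.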

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

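The test of list offsets against random sets was chosen after the phases were seen, as were the tests of chance order and grouping, depth, waveform and detection power below. Of 43 genes named here and compared, 32 had ranges that differed between conditions in the z test, 19 larger in fast and 13 in slow. The rule chose genes for large ranges and large range differences in each direction, so these counts do not stand for all genes. Of all 4776 genes compared, 1984 were larger in fast and 179 in slow. Values are cosine ranges, fast minus slow, on the log2 scale. Larger in fast were ADH2 (4.07), CTT1 (3.46), FAT3 (4.66), CTA1 (4.09), FOX2 (4.26), ADY2 (4.62), ACS1 (3.97), POX1 (4.11) and POT1 (3.61) of carbon and peroxide metabolism. So were NSR1 (2.86), YEF3 (2.43), SAM1 (2.93), RPL17B (1.54), HXK1 (3.07, overlapping YFR052C-A by 143 bases on the same strand), HXK2 (1.57), TSL1 (2.23), HSP12 (2.79), SSA3 (2.23) and CLN2 (1.99). Profile ranges of these genes differed by less: 0.84 for NSR1, 0.41 for YEF3, 0.485 for SAM1 and 0.07 for RPL17B, and from 0.38 (CLN2) to 2.43 (FOX2) for the others. Larger in slow were SRL1 (-3.28), YOR248W (-3.26), YDL218W (-3.15), YHP1 (-2.88), EGT2 (-2.48), CLB1 (-2.46), DSE4 (-2.38), INO1 (-1.93), CLN1 (-1.89), CYC1 (-1.79), HOF1 (-1.73), PDC6 (-1.32) and CDC19 (-0.77), with profile range differences from -0.59 (PDC6) to -3.625 (DSE4).

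Against the mean offset of 0.094 cycle, 8 of 18 lists had offsets between conditions that differed from random sets of genes cycling in both (permutation, adjusted over lists). The slow minus fast offsets were 0.054 cycle for mitochondrial ribosomal proteins, 0.138 for sulfur metabolism, 0.159 for oxidative phosphorylation, 0.224 for trehalose and glycogen, 0.203 for autophagy, 0.168 for heat shock genes, 0.98 for histones and 0.715 for mitosis.

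Fewer genes were called cycling in the slow than in the fast condition (3196 against 4281), an order that turned with scaling to the control RNAs (2529 against 1407) and in the repeat test (4975 against 4740). Lower depth as the whole cause was argued against: it would cost most calls at low expression, but the gap between the conditions was 18.8 percentage points in the highest and 16.6 in the lowest expression quartile, a ratio of 1.13 ± 0.142 (bootstrap SD) against a bound of 0.5. Genes called in fast alone lay 0.328 ± 0.061 (bootstrap SD) below genes called in both in median log2 expression, which a part played by depth would allow. Simulated cosine courses with a 2-fold range, at the real depths, went the other way. The slow design recovered 96.0% against 87.0% in fast, and 84.3% against 74.4% in the lowest expression quartile. Simulated noise and the number of time points differed as well, so the part of depth alone stays open. A candidate explanation is that cosine references miss a change, up or down, that lasts 1 time point. Genes called in fast alone still had a median correlation of 0.812 between the slow cycles. Their slow peaks were wider at mid-height than those of genes called in both (median 4 against 2 time points). The largest excursion up or down, however, lasted 1 time point in 62.9% against 51.0%. That excursion was downward in a larger share of genes called in fast alone than of genes called in both. RPKM values are shares of a library, so a burst in abundant genes would lower other genes in each cycle. The correlation between cycles cannot tell such lowering from a change of the gene's own. A difference in biology between the cultures stays open and was not tested.

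Cycling genes had higher expression than other genes in both conditions. Detection power rises with expression: simulated genes with a 2-fold range were recovered in 74.4% of cases in the lowest and 93.3% in the highest quartile of the fast design. In the highest quartile, cycling genes were still higher by 0.38 in fast and 0.149 in slow (permutation p = 1e-05, the smallest possible, and 0.0184). Expression here was the mean RPKM over time points, which a burst raises by itself. This comparison therefore cannot decide whether power is the cause. In the slow condition the middle quartiles showed differences of -0.013 and -0.021 (permutation p = 0.452 and 0.279). Detection power stays open as a cause.

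A random order of the time points and a random grouping of the libraries can be excluded as the source of the counts. Of 100 orders of the time points, 1 (the real one) gave as many cycling genes in each condition, against at most 3 genes in fast and 31 in slow in the other orders. Of 100 splits of the 44 libraries, 1 (the real one) gave as many genes with a level difference (246, against 0 in the others). Neighbouring time points are alike, so the orders exclude a random order and not other smooth courses, and the splits do not cover differences between single cultures.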

How the results depend on the processing

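No paired analysis was possible because the shared numbers are time points at different parts of cycles of different length. With cycle position as a covariate, 110 genes were higher and 139 lower in fast, and 3197 differed at q under 0.05 at any size. The first cycle alone gave 81 higher and 115 lower genes, with 1045 at any size. From the second cycle alone these counts were 87, 116 and 1084. Scaling to the control RNAs gave 1407 fast cycling genes, 959 in both, 170 genes higher in fast, 251 and 40 genes with a larger range in fast and slow, and a fast correlation between cycles of 0.026; the cause was not tested. Requiring a 2-fold range left 2416, 1164 and 999 genes in fast, slow and both, by construction. In both conditions q under 0.01 left 1720 and removing a linear trend 1700. The repeat test, chosen after the data were seen, gave 4975 in slow and 4316 in both. The median range difference was 0.032 for profile ranges. Shifting the second cycle earlier or later gave correlations of 0.568 and 0.57 in fast and 0.387 and 0.153 in slow. With harmonic regression 5 lists passed in fast (translation factors, sulfur metabolism, S phase and autophagy were lost), and the log2 odds of slow cycling reversed to -1.525 for cytosolic ribosomal proteins and -0.88 for ribosome biogenesis; the cause was not tested. The median level of ribosome biogenesis became 0.044 under control scaling, which moved the median of all genes to 0.196, so the list stayed below it. The fast length difference passed the threshold at q under 0.01 (0.069), at 10 RPKM (-0.136), with harmonic regression (0.152) and the repeat test (0.622); the slow one reversed to -0.013 at 10 RPKM.

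Leaving out 1 library gave 4148 to 4392 fast, 2903 to 3304 slow and 2441 to 2837 shared cycling genes, and 229 to 275 genes with a level difference (98 to 123 higher, 125 to 154 lower). Of the main results under other alternatives, 94 values kept their call or stayed within a set tolerance of the main value. For counts this tolerance was wide. It took in slow counts of 2172 with a linear trend removed and 2186 at q under 0.01, against 3196. With the trend removed, 64.4% of the main slow calls remained. Another 10 of the values were weaker, 7 stronger, 6 moved and 1 reversed. Among named genes and lists, 1708 values stayed the same in this sense, 48 lost and 17 gained the threshold, 8 moved and 3 reversed. Of simulated 0.5 log2 ranges, 15.5% were recovered in the fast and 58.0% in the slow design. The simulation used the depth of each library, which was higher on average in fast (11.5 against 9.95 M reads). Lower depth therefore cannot be the cause of the lower fast recovery. The designs also differed in simulated noise (coefficient of variation 14.1% in fast, 10.4% in slow) and in time points (20 and 24). The parts of these were not separated.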

Other observations

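The choice of gene groups here followed from seeing the data; the tests of scaling and of the interval from histones to mitotic genes, and the spread given for the change of the mating median, were chosen after the result was seen. Genes known for expression at the transition from M to G1 phase were not among the fixed lists. All 9 genes chosen for it cycled in the fast and 7 in the slow condition. In the slow condition CTS1 (range 2.77 on the log2 scale), DSE1 (2.98), PCL9 (2.88) and SCW11 (2.63) cycled with phases of 0.420, 0.404, 0.368 and 0.385. In the fast condition their ranges were 1.24, 1.17, 1.66 and 1.29, with phases of 0.870, 0.810, 0.733 and 0.790. Others had fast and slow ranges of 1.54 and 2.34 (DSE2), 0.78 and 2.21 (DSE3) and 1.77 and 1.81 (ASH1); SIC1 (0.82 and 0.72) and CHS1 (1.55 and 0.32) missed the threshold in slow (exact JTK test). CTS1 and DSE1 were higher in fast by 1.60 ± 0.30 and 1.58 ± 0.31 on the log2 scale (limma, SE), while CHS1 was lower (-1.11 ± 0.16).

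The a-specific mating genes were higher in the fast condition: all 7 rose at q under 0.05 (limma, Benjamini-Hochberg), with a median log2 change of 1.44, among them STE6 (1.45 ± 0.25, SE), BAR1 (1.44 ± 0.33) and MFA1 (1.23 ± 0.28). Of 4 alpha-specific genes, MF(ALPHA)1 rose, while STE3 (-0.15), SAG1 (-0.06) and MF(ALPHA)2 (-0.12) did not pass. Of 8 haploid-specific genes, STE4 (0.57) and FAR1 (1.28) rose at q under 0.05, and only FAR1 by at least 2-fold; of all 5820 genes, 2225 differed at that q in either direction. One hypothesis was that cells able to express haploid mating genes made up more of the fast culture. It required a median of at least 0.5 over members not seen beforehand. That median was 0.413 ± 0.283 (bootstrap SD), short of the bound by less than its spread, though above 99.99% of random matched lists. These 16 members included a-specific genes. Taken alone, the haploid-specific genes had a median of 0.219 and the alpha-specific genes one of -0.088. Both lay within the middle 95% of random matched lists, whose upper ends were 0.241 and 0.377. Scaling moves all genes alike between the conditions, so by construction it cannot set mating genes apart from other genes. The 19 mating genes did stand apart, but 3 of them were seen beforehand to be high. Their excess is therefore no independent test of scaling, and no conclusion is drawn from it. The median of the 19 genes lay 0.653 ± 0.341 (bootstrap SD) above that of all tested genes as deposited. The upper end of the middle 95% of random matched lists was 0.174. Under both other scalings the excess was 0.652 and 0.658. Subtracting the median of all genes removes a scaling factor, so this agreement was built in. With medians over time points the median was 0.512 against 0.654 (bootstrap SD of the change 0.175). The value of 0.512 lies within this spread of the bound of 0.5. A difference carried by a few time points therefore cannot be told apart by this test from one over the whole cycle. The a-specific genes did vary over the fast cycle: all 7 cycled there, with ranges from 1.67 (ASG7) to 3.75 (BAR1) on the log2 scale. Their fast phases ran from 0.77 (STE6) to 0.90 (MFA1). In the slow condition only MFA1 and AGA2 of these passed (exact JTK test).

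Mitotic genes moved against histone genes between the conditions. From histones to mitosis, the mean phases were 54.1 ± 2.6 min apart in fast and 60.8 ± 9.8 min in slow (bootstrap SD over genes), a difference of 6.7 min, while as a share of the cycle they were 0.416 and 0.141 apart. One hypothesis is that this interval may be fixed in minutes rather than in cycle length. It was then tested on the M/G1 genes, and there it failed: the intervals were 90.0 ± 2.9 and 156.9 ± 9.1 min, 63.1 min apart when the 130 min cycle is taken into account, against a bound of 36 min. Slow samples were 36 min apart, and 5 histone genes entered the slow value.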
